A study of Homo sapiens with 8 samples.

How the data were processed

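Bulk RNA-seq was analysed from 8 libraries of the human cell line Ea.hy926, 4 from the parental line and 4 from its Rho0 derivative. Both lines were collected at confluence as biological replicates, per the labels' protocols. RNA was extracted with RNAzol, treated with DNase and precipitated with lithium chloride, and libraries were made from 2 ng of total RNA with a strand-specific kit that enriches polyadenylated RNA, per the labels' protocols.

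The authors deposited 2 tables. The not-normalized table holds estimated counts for 38010 Ensembl gene IDs, with column totals that differ between samples and many values that are not whole. The submitters' processing notes name kallisto, edgeR, limma and the genome build GRCh38, without versions or roles. The annotation release behind the counts is not given in the sources used here. The normalized table holds 12885 genes on a log2 scale. Of 11391 genes compared between the tables, with a count of at least 20, 11138 (97.8%) equalled log2 of the deposited estimated counts times 1 factor per sample, plus 1, within a relative tolerance of 0.001. How those factors were made by the authors is not given in the sources used here. No column in either table belonged to a sample outside the 8.

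Gene names came from a table of gene IDs and symbols, which named 29168 of the 38010 IDs, and from GENCODE release 29 (GRCh38), which brought the total to 34284. The 3726 unnamed IDs are not in that annotation and held 1.43% to 1.75% of each library's counts. Of 908 genes in the fixed lists, 906 matched a symbol. Coordinates are those of GENCODE 29. The named IDs were almost all protein-coding genes (19555) or pseudogenes (14256).

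Estimated counts were rounded to whole numbers and fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood F-test with group as its term. P-values were adjusted by Benjamini and Hochberg over the 15184 genes tested, of which 13382 were protein-coding, and genes were called at an adjusted p of 0.05. CPM values were computed by edgeR over the TMM-scaled library size. The standard error of a log2 fold change is its size divided by the square root of F. Fold changes against a group with no counts are lower bounds against 3 counts in each library of the group. As a mean over libraries this is 0.138 CPM for the parental line and 0.127 CPM for Rho0. For genes with 1 to 3 counts in a group, the ratio of the groups is given with an exact 95% interval. Such bounds and intervals cover counting error alone.

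Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 36 lists. The same test was run with the correlation estimated from the data, and fry was run as a further test. The lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, with additions that are identified where they are used. Named genes are the 13 protein-coding genes of mitochondrial DNA, the 8 genes with the largest change in each direction, up to 3 members of each list and 8 fixed genes. Genes among the 8 had a mean of at least 10 CPM in the higher group and groups that did not overlap. They had a symbol that is not a clone or locus name and were neither mitochondrially encoded nor Y-linked. List examples had the largest changes among called members with at least 5 CPM in the higher group. A further set of 5 lower genes, taken after leaving out nuclear copies of mitochondrial genes, was chosen after the values were seen.

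Libraries held 11721708 to 37203507 estimated counts, so 1 count was worth 0.0269 to 0.0853 CPM. The biological coefficient of variation was 13.7%. On simulated counts with 50 genes changed at each fold size, drawn from the means and library sizes of this comparison with 14919 genes tested, the fit called 52% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold and at 8-fold. Of its 183 calls, 10 were false. All other genes, also those of mitochondrial DNA, had equal means in both lines in this simulation. It therefore does not cover the effect of the scaling on the real calls. No pair of libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 4.21. Shares of libraries were compared with a two-sided exact permutation test over 70 arrangements, in which the smallest possible p is 0.0286.

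The alternatives were DESeq2 size factors, library size without TMM, totals without mitochondrially encoded genes, no filter, a filter of 50 counts in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a robust fit, limma-trend on the deposited log2 table, a replicate block and leaving out each library. A correction of each library for transcript length and GC content (medians over GENCODE 29 transcripts, known for 93.7% of genes tested) was added after seeing the data. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Levels of XIST and of Y-linked genes were left out. Values of 3 further genes that the rule named are not reported here.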

Results

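Gene expression was measured in confluent cultures of Ea.hy926, a line made by fusing human umbilical vein endothelial cells with A549 lung carcinoma cells. The parental line was compared with a Rho0 line that is deficient in oxidative phosphorylation, Rho0 being the usual name for cells depleted of mitochondrial DNA. Each line gave 4 biological replicates, and the comparison asks what loss of respiration changes in cells grown to confluence, with autophagy and stress resistance as the stated interest. The parental libraries held 24390753, 28599386, 24233182 and 23366190 estimated counts in replicates 1 to 4. The Rho0 libraries held 32178578, 11721708, 20316792 and 37203507. Depth varied more within Rho0, and an exact permutation test did not separate the lines by depth (two-sided p = 0.971). The number of genes with at least 10 counts was 14677 ± 208 (SD, n = 4) and 15327 ± 1081 (SD, n = 4), with an exact permutation p of 0.314. In a principal component analysis of log2 CPM, the component with the largest share of the variance (78.7%) separated the lines. Parental libraries lay between -66.97 and -61.76 on it and Rho0 libraries between 56.22 and 72.55. Rho0 replicate 4 lay farthest from the other libraries on the next component (6.24% of the variance), at 35.28. Rho0 replicates 1 to 4 lay in numerical order on it, at -23.73, -16.82, 0.46 and 35.28. Of the fixed genes, ATG4B, ULK1, TFEB and GDF15 fell and PRKAA1 and TFAM rose steadily from Rho0 replicate 1 to 4. MAP1LC3B and SQSTM1 did not change steadily. The reason for this order was not tested.

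The mRNAs encoded by mitochondrial DNA, which code for core subunits of respiratory complexes and of ATP synthase, were nearly absent from the Rho0 libraries. They made up 18.5 ± 2.21% (SD, n = 4) of the parental libraries and 0.0409 ± 0.0720% (SD, n = 4) of the Rho0 libraries (two-sided exact permutation p = 0.0286, the smallest that 70 arrangements allow). All 13 fell, with a median log2 fold change of -9.25 and a range from -9.18 for MT-CO1 to -9.64 for MT-ND3. The cytochrome oxidase subunit gene MT-CO1 (chromosome M, 5904 to 7445) went from 54332 ± 7879 CPM to 94.1 ± 168 CPM (SD, n = 4 each; log2 fold change -9.18, SE 1.53, edgeR adjusted p = 4.9e-04). Residual levels differed among the Rho0 libraries. The share was 0.00431% in replicate 1, 0.149% in replicate 2, 0.00756% in replicate 3 and 0.00296% in replicate 4. Without Rho0 replicate 2 the median log2 fold change of the 13 genes was -12.25. As a list they were lower by camera (adjusted p = 1.6e-07), with an adjusted p of 0.402 with an estimated correlation, and all 13 were also lower when adjusted over the list alone.

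**Figure D1:**
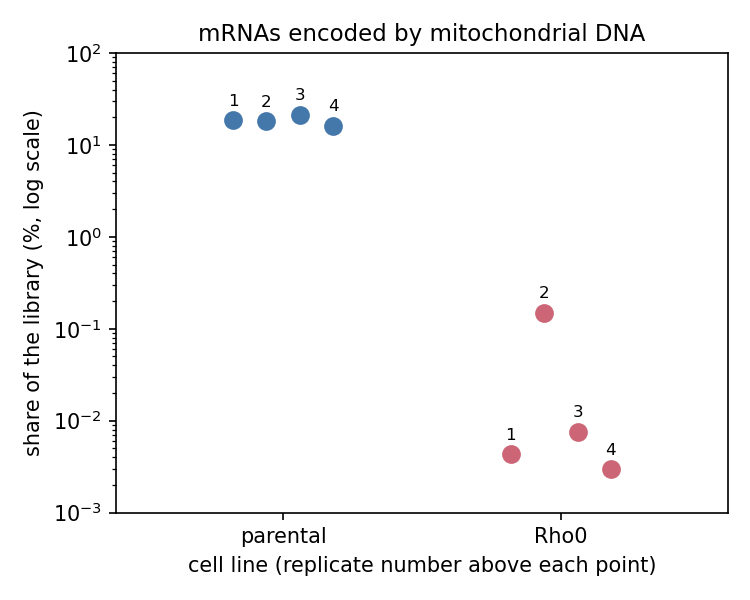
Share of each library's estimated counts (%, log scale) in the 13 mRNAs encoded by mitochondrial DNA, with 1 point per library and its replicate number above it. The parental libraries lie between 16.0% and 21.4% and the Rho0 libraries between 0.00296% and 0.149%, with Rho0 replicate 2 highest of its group.

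Expression differed widely between the lines. Of 15184 genes tested, 4399 were higher and 3858 lower in Rho0 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 0.05), so that 53.3% of the called genes were higher. With a log2 fold change of at least 1 in size, 1330 were higher and 836 lower. The balance of directions depended on the scaling of the libraries and on the method. With the DESeq2 Wald test, 4031 genes were higher and 4098 lower (49.6% higher), and after a correction for transcript length and GC content, added after seeing the data, 4396 and 4834 (47.6% higher). TMM factors were 0.801 to 0.921 in the parental line and 1.11 to 1.19 in Rho0. With libraries scaled by size alone, the median log2 fold change of all genes moved from 0.05 to 0.44, 8583 genes were called higher and 1540 lower (84.8% higher), and 80 calls turned sign. With that scaling, 2677 genes were at least 1 log2 unit higher and 490 lower. Without Rho0 replicate 2, the library that stood apart in its mitochondrial share, 3983 genes were higher and 3665 lower. P-values measure the spread between these cultures of 1 parental and 1 Rho0 line, and a difference between lines that is unrelated to respiration cannot be told from its effect in this design.

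The genes with the largest rises were close to silent in the parental line. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis (chromosome 1, 186671791 to 186680427), had no count in the parental libraries and 24.8 ± 5.0 CPM (SD, n = 4) in Rho0, at least 180-fold higher. The endothelial adhesion receptor gene ADGRL4 (chromosome 1, 78889764 to 79006718) had 3 counts in the parental libraries together and 46.4 ± 8.57 CPM in Rho0, a ratio of 1406 with a 95% counting interval of 481 to 6821. RTL8B had a ratio of 945 (interval 261 to 7805), and CELF2, an RNA-binding splicing regulator, a ratio of 564 (interval 156 to 4664). ALDH1A1, a retinaldehyde dehydrogenase, rose from 0.160 ± 0.0953 to 61.5 ± 7.29 CPM (log2 fold change 8.55, SE 0.21, edgeR adjusted p = 1.2e-09). The formin gene FHOD3 also rose (log2 fold change 8.71, SE 0.17). The pseudogene FAM90A13P was at 0 in the parental libraries and 22.8 ± 3.56 CPM in Rho0, at least 165-fold higher, but it belongs to a multicopy family whose reads are hard to assign, so its value is uncertain. Without parental replicate 4, the fitted log2 fold change of ADGRL4 moved from 10.22 to 11.19.

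Among genes that fell, TFF3, a secreted trefoil peptide gene (chromosome 21, 42311667 to 42315651), went from 11.1 ± 0.955 CPM (SD, n = 4) to no count, at least 87.9-fold lower in Rho0. NTRK2, the receptor for brain-derived neurotrophic factor (chromosome 9, 84668551 to 85027070), went from 12.1 ± 0.774 CPM to 1 count in Rho0 replicate 3, a ratio of 1411 with a counting interval of 253 to 55783. The T-cell receptor constant gene TRBC2 was at least 102-fold lower, from 12.98 ± 1.93 CPM, although it shares sequence with its neighbour copy and is uncertain for that reason. MTND1P23 (at least 117-fold lower), MTRNR2L11, MTND2P28, MTRNR2L10 and MTCO1P12 (log2 fold changes -10.27, -10.24, -10.20 and -10.02) are nuclear copies of mitochondrial genes, and their counts can come from mitochondrial reads. With those 5 left out, a choice made after the values were seen, the next genes were THY1, LCP2, FRMD3, GRAP and SLITRK4. THY1, a surface glycoprotein of fibroblasts and activated endothelium, fell from 18.9 ± 1.61 to 0.0661 ± 0.0667 CPM (log2 fold change -8.61, SE 0.31). LCP2, an adaptor of immune receptor signalling, had a ratio of 457 (interval 156 to 2218), and FRMD3, GRAP and SLITRK4 had log2 fold changes of -6.68, -6.30 and -5.78. Single libraries moved several of these fitted log2 values. NTRK2 was at -11.30 without Rho0 replicate 3, against -9.81, but no NTRK2 count is then left in Rho0. Its value of -11.30 is therefore not a measured size. LCP2 was at -9.71 without Rho0 replicate 2 and -7.97 without Rho0 replicate 4, against -8.58. Without Rho0 replicate 4, THY1 was at -7.98 and FRMD3 at -7.38. Without Rho0 replicate 2, MTRNR2L11 was at -11.87, MTND2P28 at -12.00, MTRNR2L10 at -11.68 and MTCO1P12 at -12.04, and without Rho0 replicate 4 the last 3 were at -9.60, -9.57 and -9.38.

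Genes of stress responses to amino acid shortage, oxidants and misfolded protein were higher in Rho0. Of 31 genes of the ATF4-driven integrated stress response, 25 rose and 1 fell, with a median log2 fold change of 0.61 (camera adjusted p = 1.1e-06, and adjusted p = 0.273 with an estimated correlation). CHAC1, which degrades glutathione, rose from 0.938 ± 0.194 to 8.55 ± 1.61 CPM (log2 fold change 3.19, SE 0.20, edgeR adjusted p = 3.3e-07). CBS, of transsulfuration, rose 6.26-fold, and the cystine carrier SLC7A11 rose 4.85-fold. GDF15, a secreted stress cytokine and a member of the same list, had 186 ± 8.58 and 206 ± 22.8 CPM and did not pass the test (log2 fold change 0.14, adjusted p = 0.184). Targets of NRF2, the regulator of the oxidant response, had 15 of 23 members higher and 2 lower (median 0.53, adjusted p = 0.0023, and adjusted p = 0.241 with an estimated correlation). Examples with at least 5 CPM in the higher group were TRIM16L (4.00-fold), AKR1C3 (3.66-fold) and heme oxygenase HMOX1 (2.38-fold). The largest change of the list was that of AKR1B10 (log2 fold change 2.51). In the endoplasmic reticulum unfolded protein response, 12 of 18 rose and 0 fell (median 0.28, adjusted p = 0.0067, and adjusted p = 0.195 with an estimated correlation), including the chaperones CANX (2.08-fold) and HSP90B1 (1.76-fold) and the degradation factor SEL1L (2.00-fold). Hypoxia-inducible targets had 14 of 18 members higher and 0 lower (median 0.43, adjusted p = 0.0023, and adjusted p = 0.195 with an estimated correlation), with the collagen lysyl hydroxylase PLOD2 up 3.57-fold, the MYC antagonist MXI1 1.91-fold and INSIG2 1.80-fold. Adjusted over the list alone, these 4 lists had 26, 15, 14 and 14 members higher and 1, 2, 0 and 0 lower. Serine and one-carbon metabolism, an output of ATF4, went both ways, with 8 of 18 genes higher and 6 lower, also when adjusted over the list alone (median 0.07, adjusted p = 0.889). The mitochondrial folate enzyme ALDH1L2 rose 17.1-fold and the serine synthesis enzyme PSAT1 3.35-fold, while the cytosolic folate enzyme ALDH1L1 fell by 1.65 on the log2 scale. Antioxidant enzymes also divided (5 of 21 higher and 9 lower, also when adjusted over the list alone; median -0.15, or 0.23 when scaled by library size alone; adjusted p = 0.379). GPX8 rose 2.77-fold, and the peroxiredoxins PRDX4 and PRDX6 fell by 0.85 and 0.77.

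Core autophagy genes were not called as different from other genes, while lysosomal genes were mostly higher. Of 39 genes of the core autophagy machinery, 13 rose and 9 fell (15 and 10 when adjusted over the list alone), with a median log2 fold change of 0.08 (camera adjusted p = 0.769). By fry, which tests a list against no change and not against other genes, core autophagy and the autophagy receptors were higher (adjusted p = 0.024 and 0.040), although the median of the receptors was -0.07. The initiation scaffold gene RB1CC1 rose 2.29-fold (SE 0.24 on the log2 scale, edgeR adjusted p = 0.0017) and VMP1, of autophagosome formation, 1.66-fold, whereas the LC3 protease gene ATG4A fell by 0.91. MAP1LC3B (chromosome 16, 87383995 to 87404779), which encodes the autophagosome membrane protein LC3B, went from 110 ± 6.17 to 91.3 ± 3.11 CPM (SD, n = 4 each; log2 fold change -0.27, SE 0.07, edgeR adjusted p = 0.0058), but it was at 0.13 and not called when scaled by library size alone. SQSTM1, the cargo receptor p62, went from 276 ± 12.3 to 229 ± 33.7 CPM (-0.27, SE 0.10, adjusted p = 0.0497), but it was at 0.12 and not called with that scaling. ULK1, the initiating kinase, went from 45.4 ± 2.21 to 54.2 ± 4.68 CPM (0.25, SE 0.08, adjusted p = 0.019). The call of SQSTM1 was held in 8 of 19 alternatives (adjusted p = 0.0145 to 0.242) and that of ULK1 in 14 of 19 (2.6e-05 to 0.078). It was lost for SQSTM1 without any 1 of parental replicates 1 to 4 (adjusted p = 0.064, 0.087, 0.110 and 0.098) or without Rho0 replicate 2 (0.079) or 3 (0.077), with either other filter on low counts (0.058 and 0.071), without mitochondrial genes in the totals (0.051) and with a replicate block (0.052). For ULK1 it was lost without parental replicate 1 (0.061) or 2 (0.067) and without Rho0 replicate 1 (0.068), 2 (0.078) or 3 (0.053). The protease gene ATG4B had 43.7 ± 1.49 and 48.5 ± 6.08 CPM (0.15, SE 0.09, adjusted p = 0.200), the lysosomal regulator TFEB 2.37 ± 0.304 and 2.87 ± 0.323 CPM (0.27, SE 0.15, adjusted p = 0.166) and the AMPK catalytic subunit PRKAA1 105 ± 4.32 and 102 ± 16.5 CPM (-0.04, SE 0.10, adjusted p = 0.762). Without Rho0 replicate 4, ATG4B was called at 0.22 (adjusted p = 0.024) and PRKAA1 at -0.17 (adjusted p = 0.049). When scaled by library size alone, ATG4B, TFEB, GDF15 and PRKAA1 were called, at 0.54, 0.66, 0.53 and 0.35, the last with its sign turned. After a correction for transcript length and GC content, added after seeing the data, they were called at 0.25, 0.38, 0.22 and -0.23.

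**Figure D2:**
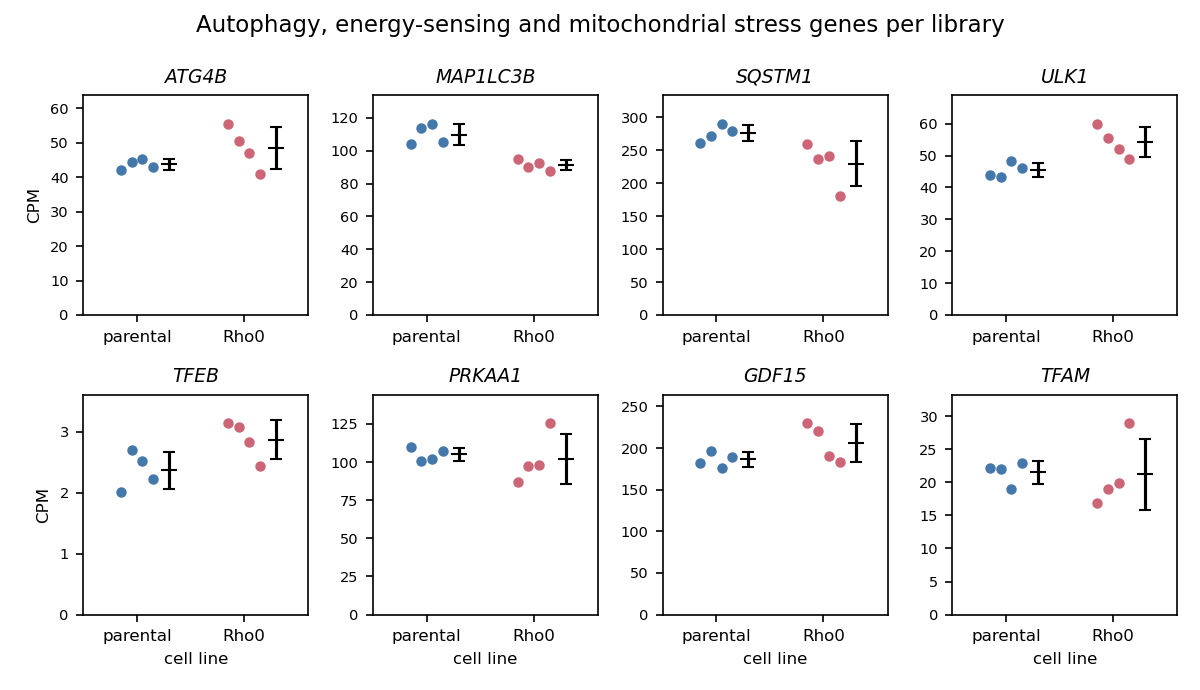
CPM per library (TMM-scaled) of the 8 genes fixed in advance, with points for the 4 libraries of each line and a bar at the mean with its SD beside them. MAP1LC3B and SQSTM1 were lower and ULK1 higher in Rho0 with TMM scaling (adjusted p = 0.0058, 0.0497 and 0.019), the call of SQSTM1 was held in 8 of 19 alternatives, MAP1LC3B and SQSTM1 change sign when scaled by library size alone, and the other 5 did not pass the test.

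Autophagy and mitophagy receptors had 5 of 17 members higher and 4 lower (4 and 2 adjusted over the list alone), with a median of -0.07 (0.32 when scaled by library size alone), a mean of 0.28 and a camera direction of up, so that these differed in sign (adjusted p = 0.889). The mean rested on RETREG1, singled out after its values were seen, at 0.0245 and 0.635 CPM (log2 fold change 4.57), without which the mean of the other 16 was 0.0090. TAX1BP1 rose 1.69-fold and the mitochondrial receptors FKBP8 and PHB2 fell by 0.47 and 0.45. FKBP8 lost its call without parental replicate 2 or 3 or without Rho0 replicate 3 (log2 fold changes -0.45, -0.44 and -0.43), and FKBP8 and PHB2 lost theirs when scaled by library size alone. Of 47 lysosomal genes, 28 rose and 8 fell, also when adjusted over the list alone (median 0.44, adjusted p = 0.0056; adjusted p = 0.402 with an estimated correlation). The ceramidase ASAH1 rose from 3.97 ± 0.385 to 20.4 ± 3.83 CPM, the cathepsin CTSF 4.27-fold and the galactosidase GLB1 2.68-fold. Subunits of the lysosomal proton pump had 3 of 17 members higher and 4 lower, also adjusted over the list alone (median 0.01, mean -0.06, camera direction down, adjusted p = 0.817). ATP6V0E2, ATP6V0D1 and ATP6V1F had log2 fold changes of -0.71, -0.59 and -0.45, the last 2 of them not called when scaled by library size alone. Regulators of AMPK, mTORC1 and TFEB had 5 of 23 higher and 8 lower, also adjusted over the list alone (median -0.04, or 0.35 when scaled by library size alone, mean 0.00048, adjusted p = 0.763). The AMPK subunit PRKAG2 fell by 0.92, and the mTORC1 subunit RPTOR and the folliculin gene FLCN rose 1.73-fold and 1.65-fold.

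Nuclear genes of complex I and of the mitochondrial ribosome were lower relative to other genes, while the nuclear lists of complexes II to V did not pass the test. The complexes were not tested against each other. The median of complex III, with 10 genes, lay below that of complex I, with 37. Of 37 nuclear subunits of complex I, 20 fell and 2 rose (21 and 2 when adjusted over the list alone), with a median of -0.33, or 0.06 when scaled by library size alone (camera adjusted p = 0.0014, and adjusted p = 0.694 with an estimated correlation). NDUFC1 went from 19.0 ± 0.530 to 9.06 ± 0.532 CPM (SD, n = 4 each; log2 fold change -1.07, SE 0.08, edgeR adjusted p = 1.5e-06), NDUFA8 from 33.8 ± 1.58 to 16.8 ± 1.63 CPM, and NDUFB9 had a log2 fold change of -0.98. Of 76 mitoribosomal genes, 34 fell and 8 rose, also adjusted over the list alone (median -0.20, or 0.19 when scaled by library size alone; adjusted p = 0.0063, and adjusted p = 0.732 with an estimated correlation), led by MRPL52 (-1.39) and MRPL13 (-0.79) against a rise of MRPS25 (0.77). With scaling by library size alone, the medians of complex I and the mitoribosome differed from that of all genes by -0.39 and -0.26, and the call of the mitoribosome was lost (adjusted p = 0.283). Complex II had 4 of 7 members lower and 1 higher (median -0.17, or 0.22 by library size alone; adjusted p = 0.395), complex III 6 of 10 lower and 1 higher (median -0.42, adjusted p = 0.068), complex IV 4 of 12 lower and 2 higher (median -0.19, or 0.20; adjusted p = 0.311) and complex V 4 of 16 lower and 3 higher (median -0.13, or 0.26; adjusted p = 0.278). The counts adjusted over the list alone were the same, apart from 2 higher in complex III. The camera call of complex III was gained without parental replicate 1 (0.049) or Rho0 replicate 1 (0.034). Among subunits and assembly factors of complex II, SDHB and SDHAF2 had log2 fold changes of -0.46 and -0.48 and SDHAF1 of 0.50. CYC1, UQCR11 and UQCRQ of complex III had -0.93, -0.76 and -0.72. In complex IV the values were -0.69 for COX8A, -0.63 for COX5A and 0.44 for COX5B. In complex V they were -0.72 for ATP5MF, -0.51 for ATP5MC2 and -0.39 for ATP5F1B, which was at 0.00061 and not called when scaled by library size alone. SDHB, SDHAF2, COX5A and ATP5MC2 also lost their calls with that scaling.

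Genes of mitochondrial DNA maintenance showed no common direction, with 3 of 24 higher and 8 lower, also adjusted over the list alone (median 0.04, mean -0.02, camera direction down, adjusted p = 0.741). TFAM, which packages mitochondrial DNA, had 21.5 ± 1.70 and 21.2 ± 5.32 CPM (log2 fold change -0.01, SE 0.15, edgeR adjusted p = 0.948), and its sign changed among the alternatives, from -0.27 with the length and GC correction (called, adjusted p = 0.0070) to 0.38 with scaling by library size alone. POLG2 rose by 0.64, and PRIMPOL and DGUOK fell by 0.70 and 0.62, PRIMPOL without a call by library size alone. Mitochondrial chaperones and proteases had 5 of 17 higher and 6 lower, also adjusted over the list alone (median -0.11, or 0.28 when scaled by library size alone; adjusted p = 0.687). The stress-responsive proteases YME1L1 and OMA1 rose by 0.82 and 0.65 and CLPP fell by 0.62, a call lost with that scaling. In the citric acid cycle and pyruvate entry, 13 of 26 genes fell and 1 rose, also adjusted over the list alone (median -0.25, or 0.14 when scaled by library size alone; adjusted p = 0.0099, and adjusted p = 0.376 with an estimated correlation). Pyruvate carboxylase PC went from 40.4 ± 2.72 to 14.4 ± 2.31 CPM, and OGDH and GOT2 fell by 0.89 and 0.75. Of 23 genes of glycolysis and lactate export, 10 fell and 2 rose, also adjusted over the list alone (median -0.31, or 0.08 by library size alone; adjusted p = 0.037, and adjusted p = 0.738 with an estimated correlation). TPI1 and GPI fell by 1.10 and 0.92, and the glycolytic activator PFKFB3 rose 2.44-fold. The glycolysis call by camera was lost without Rho0 replicate 3 (adjusted p = 0.059) or 4 (0.078). It was also lost with a filter of 50 counts in 4 libraries (0.071) and with the length and GC correction (0.089). By library size alone neither of the citric acid cycle and glycolysis lists was called (adjusted p = 0.193 and 0.207), with medians below the 0.44 of all genes. Fatty acid oxidation had 8 of 19 genes lower and 3 higher, also adjusted over the list alone (median -0.12, or 0.27 by library size alone; adjusted p = 0.0503), with HADH, CPT2 and ECHS1 lower by 1.09, 0.79 and 0.74. It was called without parental replicate 1 (0.043) or 3 (0.045) and without Rho0 replicate 1 (0.020) or 2 (0.047).

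Genes of cholesterol synthesis and of cell division were mostly lower in Rho0. Of 23 genes of cholesterol synthesis and uptake, 21 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 fold change of -1.03 (camera adjusted p = 6.7e-11, and adjusted p = 0.058 with an estimated correlation). MSMO1, a sterol methyl oxidase gene (chromosome 4, 165327623 to 165343160), went from 40.3 ± 3.09 to 8.50 ± 1.24 CPM (SD, n = 4 each; log2 fold change -2.25, SE 0.12, edgeR adjusted p = 8.6e-08), and DHCR7 fell by 1.93. Of 25 S phase genes, 22 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.75, adjusted p = 2.5e-08, and adjusted p = 0.259 with an estimated correlation), including the helicase subunit MCM7 (-1.57) and the replication factors CDT1 (-1.39) and CDC45 (-1.36). Of 25 genes of G2 and mitosis, 19 fell and 0 rose, also adjusted over the list alone (median -0.79, adjusted p = 6.6e-07, and adjusted p = 0.241 with an estimated correlation), including AURKB (-1.32), CCNB2 (-1.31) and CCNA2 (-1.29). Growth arrest genes of the p53 pathway had 9 of 18 members higher and 4 lower, also adjusted over the list alone (median 0.17, adjusted p = 0.147). GADD45B rose 4.40-fold, MDM2 2.54-fold and TP53INP1 2.14-fold. Regulators of apoptosis of the BCL2 family had 5 of 13 higher and 4 lower (6 and 5 adjusted over the list alone; median 0.08, adjusted p = 0.817), with BMF higher by 0.83 and log2 fold changes of -1.06 for BAK1 and -0.56 for BID, which lost its call when scaled by library size alone. Of 52 cytosolic ribosomal protein genes, 24 fell and 7 rose, also adjusted over the list alone (median -0.25, or 0.14 when scaled by library size alone; adjusted p = 0.015, and adjusted p = 0.80 with an estimated correlation). RPS2 and RPSA fell by 0.75 and 0.70. The ribosomal call was lost without Rho0 replicate 4 (adjusted p = 0.071) and with scaling by library size alone (adjusted p = 0.247).

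**Figure D3:**
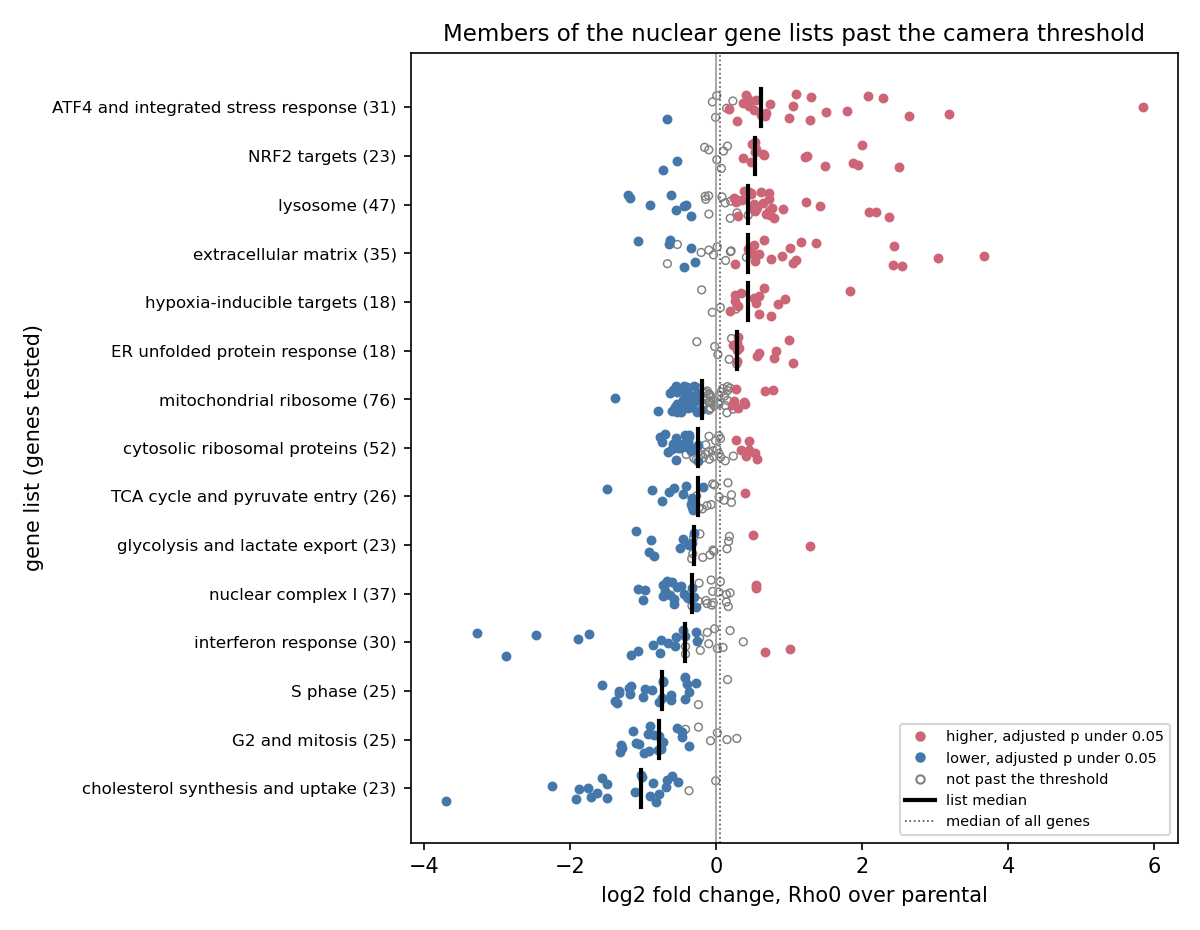
Log2 fold change (Rho0 over parental, horizontal axis) of each tested member of the 15 nuclear lists called by camera, none of which stayed called with an estimated correlation (adjusted p = 0.058 to 0.80), with a black bar at each list's median and a dotted line at the median of all genes (0.05). Medians run from -1.03 for cholesterol synthesis to 0.61 for the integrated stress response, and those of complex I, the mitoribosome, the ribosomal proteins, the citric acid cycle and glycolysis turn positive when libraries are scaled by size alone.

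Interferon response genes were mostly lower and matrix genes mostly higher in Rho0. Of 30 interferon response genes, 17 fell and 2 rose, also adjusted over the list alone (median -0.42, camera adjusted p = 4.0e-04; adjusted p = 0.241 with an estimated correlation). OASL and OAS2, antiviral synthetase family genes, went from 11.2 ± 0.446 to 1.19 ± 0.220 CPM and from 81.1 ± 5.54 to 14.8 ± 1.90 CPM, and ISG20 fell by 1.89. Among 19 NF-kB and inflammatory genes, 10 fell and 5 rose, also adjusted over the list alone, and the list did not pass (adjusted p = 0.068; adjusted p = 0.460 with an estimated correlation). Their median was -0.64, also with PTGS2 at its lower bound, while the fitted mean was 0.07 and the mean with PTGS2 at its bound was -0.18. The cytokines CSF2 and CCL2 went from 24.3 ± 1.06 to 2.60 ± 0.518 CPM and from 45.6 ± 5.58 to 4.95 ± 0.232 CPM. Of 35 extracellular matrix genes, 19 rose and 6 fell, also adjusted over the list alone (median 0.43, adjusted p = 0.0080; adjusted p = 0.402 with an estimated correlation). Fibronectin FN1 (chromosome 2, 215360440 to 215436172) rose from 136 ± 12.6 to 1731 ± 338 CPM (SD, n = 4 each; log2 fold change 3.67, SE 0.16, edgeR adjusted p = 2.2e-08), COL6A1 rose 8.22-fold and CCN2 5.84-fold.

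Markers of the cell types behind the hybrid line changed in both directions. Endothelial markers had 8 of 26 members higher and 11 lower, also adjusted over the list alone (median -0.07, or 0.32 when scaled by library size alone; adjusted p = 0.658). The VEGF receptor gene KDR rose from 13.8 ± 0.794 to 131 ± 13.5 CPM, and EMCN and LYVE1 had log2 fold changes of -4.24 and -3.46. Epithelial markers had 3 of 14 higher and 7 lower, also adjusted over the list alone (median -0.59, adjusted p = 0.194), with log2 fold changes of 2.71 for CLDN1, -1.73 for KRT80 and -1.21 for KRT8. With scaling by library size alone this list was called (adjusted p = 0.017). Fibroblast and smooth muscle markers had 3 of 8 higher and 2 lower, also adjusted over the list alone, with a median of -0.09 (0.30 when scaled by library size alone), a mean of -0.57 and a camera direction of up (adjusted p = 0.889). FAP and ACTA2 rose 6.40-fold and 3.54-fold, against the fall of THY1. Blood cell markers had 3 of 5 higher and 2 lower, also adjusted over the list alone, with a median of 0.29, a mean of -0.20 and a camera direction of down (adjusted p = 0.938). LAPTM5 went from 242 ± 20.8 to 46.1 ± 2.61 CPM, LYZ rose 3.66-fold, and CD68 rose by 0.29 on the log2 scale, a call that was lost without Rho0 replicate 3 (adjusted p = 0.059). Of the 145 named genes, 28 lay in blocks of neighbouring genes that had shifted together between the lines, 24 of them with the sign of their block. Among these were FN1, MDM2, CYC1, GLB1, MRPS25, NDUFB9 and NDUFC1. Of all called genes in blocks, 17.8% lay in such blocks. A block's sign comes from the fold changes of its own genes, so neither count speaks for a regional cause.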

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

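The sets of nuclear genes used here to look for parental material were widened after the result of the narrowest set was seen. Within each line, a library was singled out when its gap to the nearest other library passed Dixon's 95% limit for 4 samples, as a share of their range. Of 294 such comparisons 29 passed, where chance gives about 1 in 20, and 18 of them concern mitochondrial transcripts or their nuclear copies in Rho0 replicate 2.

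In Rho0 replicate 2, mRNAs encoded by mitochondrial DNA made up 0.149% of the library against at most 0.00756% in the other Rho0 libraries. Their CPM values there were 26.1 for MT-ND6, 119 for MT-CO2, 85.1 for MT-CYB, 50.9 for MT-ND2, 93.4 for MT-ND5, 346 for MT-CO1, 11.6 for MT-ND3, 219 for MT-ND4, 45.9 for MT-ND1, 102 for MT-ATP6, 142 for MT-CO3, 41.6 for MT-ND4L and 32.7 for MT-ATP8. The nuclear copies followed, with 0.603 CPM for MTRNR2L11, 1.66 for MTND2P28, 0.226 for MTRNR2L10 and 0.377 for MTCO1P12.

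The transcripts of mitochondrial DNA in Rho0 replicate 2 stood at 0.646% of the parental level, and in the other Rho0 libraries at 0.0187%, 0.0328% and 0.0128%. Parental cells, RNA or reads in that library are a candidate explanation, and would bring nuclear transcripts of parental cells at the same share. For 13 genes at 2% or less of their parental level in the other Rho0 libraries, 24 counts were seen against 15.0 at the level of those libraries, an excess of 0.463% of the parental level with 95% limits over genes of -0.0796% and 0.963%. Mitochondrial DNA kept by some Rho0 cells is the other candidate, and the 4 gene sets tried, of 4 to 13 genes, all had limits on both sides of 0.323%, the deciding value by a rule set in advance. These explanations cannot be told apart, because too few genes are silent enough in Rho0 and this library is the shallowest.

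Other values set apart within a line belonged to single genes. In Rho0 they were NTRK2 at 0.0429 CPM in replicate 3, NDUFC1 at 8.27 in replicate 4, UQCR11 at 23.5 in replicate 1, MCM7 at 95.3 in replicate 1, CCNB2 at 19.4 in replicate 2 and BID at 10.5 in replicate 4. In the parental line they were SDHB at 36.9 CPM in replicate 3, COX8A at 64.0, ASAH1 at 3.40 and BMF at 9.36 in replicate 1, and CSF2 at 25.9 in replicate 4. The NTRK2 value is 1 count against none in the other Rho0 libraries, which passes the limit by construction.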

How the results depend on the processing

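The correction for length and GC content was chosen after seeing the data; the others were planned. Of 145 named genes, 124 kept their direction and side of the threshold in each alternative run, and the 13 mitochondrially encoded mRNAs were lower in each that tested them. Of 16 called lists, 12 kept their call in each alternative except the estimated correlation. That setting also lost the mitochondrially encoded list, in which all 13 genes fell (camera adjusted p = 0.402), so it can miss a large change. The estimated correlations of the unfolded protein response (-0.0038) and hypoxia (0.0090) lists lay below the preset 0.01. A higher correlation between genes is thus not why those calls were lost. The causes of the changes below were not tested. The filter of 50 counts in 4 libraries left 12348 genes and the setting with no filter 26141, against 15184 in the main fit. Fewer libraries enter the leave-one-out fits.

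Scaled by library size alone, 8583 genes were higher and 1540 lower, with 2677 and 490 at 1 log2 unit or more. With 50 counts in 4 libraries, 829 genes were higher by that much. With limma-trend on the deposited table, which holds 12885 genes, 4091 were higher and 3658 lower, with 746 and 528 at 1 log2 unit or more. The lower genes outnumbered the higher with the DESeq2 Wald test (4098 against 4031) and with the correction (4834 against 4396). Leaving out each library gave 3774 to 4591 higher and 3415 to 4391 lower.

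With an estimated correlation none of the 16 calls held: adjusted p was 0.273 for the integrated stress response, 0.058 for cholesterol, 0.80 for ribosomal proteins, 0.195 for the unfolded protein response and hypoxia, 0.402 for matrix, lysosome and mitochondrially encoded mRNAs, 0.241 for G2 and mitosis, interferon and NRF2, 0.738 for glycolysis, 0.732 for the mitoribosome, 0.694 for complex I, 0.259 for S phase and 0.376 for the citric acid cycle. Fry gave 0.167 for ribosomal proteins, and passed autophagy receptors (0.040), BCL2 family (0.028), blood (0.0028), complex II (0.031), core autophagy (0.024), epithelial (0.0048), fatty acid oxidation (0.0031), NF-kB (0.035), complex III (0.0042), p53 (1.0e-05) and serine metabolism (0.021).

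Library-size scaling ended the calls of ribosomal proteins (0.247), glycolysis (0.207), the mitoribosome (0.283) and the citric acid cycle (0.193), passed epithelial markers (0.017) and NF-kB (0.0033), and turned the direction of AMPK regulators and fibroblast markers (0.666), mitochondrial chaperones, mitochondrial DNA maintenance and complex V (0.906), serine metabolism (0.881) and V-ATPase (0.845), none of them called. Glycolysis was lost with 50 counts in 4 libraries (0.071) and with the length and GC correction (0.089). Fatty acid oxidation passed with DESeq2 size factors (0.045), the Wald test (0.045), voom (0.044) and no filter (0.024), complex III with the correction (0.035) and no filter (0.025), and NF-kB with limma-trend (0.037) and voom (0.044). Directions of uncalled lists turned for autophagy receptors with the correction (0.899), limma-trend (0.892) and totals without mitochondrial genes (0.881), for blood markers with 50 counts (0.868), the correction (0.899) and the replicate block (0.993), and for fibroblast markers with no filter (0.992) and without mitochondrial genes (0.891). Leaving out each library gave 0.819 to 0.997 for autophagy receptors, 0.672 to 0.974 for blood, 3.6e-04 to 0.071 for ribosomal proteins, 0.020 to 0.106 for fatty acid oxidation, 0.587 to 0.981 for fibroblast markers, 0.019 to 0.078 for glycolysis and 0.034 to 0.107 for complex III.

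Log2 fold changes reversed with library-size scaling for ATP5F1B (0.00061), MAP1LC3B (0.13), PRKAA1 (0.35), SQSTM1 (0.12) and TFAM (0.38). TFAM also reversed with 50 counts (0.014) and no filter (1.9e-05). Without single libraries PRKAA1 ranged from -0.17 to 0.0028 and TFAM from -0.22 to 0.061. Elsewhere 14 named genes lost a call in some alternative, 11 of them with library-size scaling, and 5 gained 1.

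Replicate numbers are shared by the lines but did not pair the libraries: deviations of same-numbered libraries correlated at -0.13, 0.04, 0.0019 and 0.16 across genes. With a replicate block, 4215 genes were higher and 3802 lower, 7788 of the 8257 calls were kept, and SQSTM1 was not called (adjusted p = 0.052). Depth limits the low genes most, Rho0 replicate 2 being worth 0.0853 CPM per count.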

Other observations

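Of the tests in this part, those on blocks, lists and splits were set before their results were seen, apart from the count of blocks and the runs after correction, the size bound for block ratios, the limits over genes of the lists and the correction for length and GC content itself, which were chosen afterwards. The number of random sets behind the block count was raised after first counts, close to the one given, were seen to vary with the sets drawn.

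Neighbouring genes tended to move together. The tested genes on chromosomes 1 to 22 and X were divided into 274 blocks of 50 neighbours (GRCh38, GENCODE 29), and 41 blocks had a median log2 fold change outside the range that nearly all of 400000 random sets of 50 genes kept to (-0.25 to 0.38), 24 higher and 17 lower in Rho0. Before any correction, the runs of 3 or 4 blocks were all higher in Rho0. On chromosome 5, 200 genes from 52787896 to 119637199 lay 0.60 above the median of all genes, a ratio of 1.51, with 87.5% of them above it. On chromosome 3, 150 genes from 3126916 to 42537573 had a ratio of 1.51, and on chromosome 10, 150 genes from 134465 to 46003734 a ratio of 1.45. On chromosome 2, 150 genes from 135531455 to 189761193 had a ratio of 1.32. A run on chromosome 8, 100 genes from 123013164 to 144474202, had a ratio of 0.754. Of the named genes, NDUFB9 and CYC1 lie in that run, MRPS25, GLB1 and RPSA in the run on chromosome 3, GPX8 in that on chromosome 5, FAP in that on chromosome 2, and CELF2, PFKFB3, AKR1C3 and YME1L1 in that on chromosome 10. RPSA fell by 0.70, against the direction of its block. Shifted blocks held 15.0% of the genes in blocks. They held 17.8% of the called genes on these chromosomes, a share that also counts genes in no block. A correction for transcript length, GC content and expression level changed which blocks were shifted: 27 of the 41 stayed so and 9 others became so. The runs on chromosomes 3, 8 and 10 stayed whole, 3 of 4 blocks were kept on chromosome 5 and 1 of 3 on chromosome 2. A run of 4 blocks on chromosome 4, 200 genes from 84669610 to 175019214, was lower after the correction (median log2 fold change -0.45, against -0.18 before), though only 1 of its blocks was shifted before. It holds EMCN, MSMO1, CCNA2, HADH and NDUFC1, which fell, and SLC7A11, which rose. A second run on chromosome 5, 150 genes from 141515016 to 177456286, was higher after it (0.32, against 0.41 before), with 1 of its 3 blocks shifted before, and holds LCP2, which fell.

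Chance along the gene order is argued against, since 1000 shuffles gave at most 3 such blocks against 41. After the correction for length, GC content and expression level, 36 blocks were shifted, against at most 3 in shuffles, so these properties are not the whole cause. That correction kept 65.9% of the blocks with their sign, short of the share set in advance to exclude such a bias, so a part played by these properties cannot be told apart from other causes. Of the shifted blocks, 41.5% adjoined a shifted block of the same sign, above the 24.4% that 95% of shuffles of the block order did not exceed. DNA copy number differences between the lines are a candidate explanation that cannot be told apart from other causes either, because 6 blocks had ratios above the 1.5 of a gain from 2 copies to 3 (up to 1.71) and no DNA was measured, so the starting copy number is not known.

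The nuclear lists of complex I, the mitoribosome and the cytosolic ribosome, called as lower by camera but not with an estimated correlation (adjusted p = 0.694, 0.732 and 0.80), the last also not by fry (0.167) or without Rho0 replicate 4 (0.071), and the last pair not by library size alone (0.283 and 0.247), are made of short transcripts (median length 643, 860 and 691 bases, against 1047 for all genes tested). After the correction for length and GC content, the lists still differed from the median of all genes by -0.284, -0.172 and -0.200, with upper 95% limits over genes, taken as independent, of -0.144, -0.138 and -0.100. All lie further from that median than the 0.05 set in advance for a bias of length or GC content as the whole cause. The differences also passed the wider margin set in advance for excluding that cause, but these limits did not reach it. Before the correction, genes within the lists were correlated (estimates of 0.416, 0.222 and 0.724), so the limits may be too narrow. The differences alone thus argue against length or GC content as the whole cause, and a part played by it stays open. The freeing of reads by the loss of mitochondrial transcripts is a change of scaling, which moves all genes alike. It therefore cannot give the lists' difference from the median of all genes, but it can move their own medians. Without mitochondrially encoded genes in totals and scaling, the differences were -0.379, -0.248 and -0.298. That setting was no test of the cause, since it barely changes the differences. Whether the lists fell in themselves stays open, because their medians depend on the scaling. They were -0.35, -0.22 and -0.26 in that setting and 0.06, 0.19 and 0.14 when scaled by library size alone. An effect of the loss of respiration on these genes stays open as a hypothesis, beside differences between the lines that are unrelated to respiration.

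Chance division of the libraries is argued against for the count of called genes, as far as 35 splits can show. Each other split mixes the lines, so their difference enters the spread within its groups and lowers its count. Among the 35 splits of the 8 libraries into 4 and 4, only the real split, 1 of 35, gave as many as its 8257 genes. The highest of the others gave 0 genes with the edgeR test, 2043 genes at an unadjusted p of 0.05 and 2 genes with limma-voom.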
